A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

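The study measured transcript levels in a Saccharomyces cerevisiae culture of the spo11-Y135F mutant at 1, 2, 3, 4, 5, 6 and 8 h of a meiotic time course. Per the labels' protocols, cells were collected on filters, total RNA was extracted with hot acid phenol, polyadenylated RNA was isolated, and aminoallyl-labelled cDNA was coupled to dyes, with Cy5 for the time point and Cy3 for a mixture of mRNA from all time points. All 7 arrays have the same dye orientation per the labels, so a dye effect that is constant over arrays cancels in the ratio to 0 h. The deposited values are log2 ratios: per the series' design text, the authors divided the Cy5 over Cy3 ratio of a time point by the ratio at 0 h and took log2. The design text also states 2 independent cultures as duplicates, but each time has 1 column of values, and how the cultures enter it is not given in the sources used here; each time point was therefore used as 1 sample. The titles of all 7 samples name the mutant; the descriptions of the 1 and 2 h samples do not. The array platform, scanner, background correction, normalization within or between arrays and filters on spots are not given in the sources used here. The direction of the ratio follows from the labels and the design text, and genes known to be induced in meiosis lie above 0.

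The table holds 6141 open reading frames with 1 row each, and 7 columns. The columns of 1, 2, 3, 4, 5 and 8 h have values for the same 5635 rows. The 6 h column has 5906 values: 321 rows have a value at 6 h only, 50 are empty at 6 h only, and 185 have none. The 5585 rows with a value at all 7 times were used. Column medians over these lay between -0.15 (6 h) and 0.03 (1 h), and their standard deviations between 0.84 (2 h) and 1.49 (6 h). Systematic names were matched to locus tags of the R64 reference table for gene names and for the order of genes; 5655 matched and 486 did not, and the unmatched keep their systematic name. No coordinates are given, since the build behind the array is not named. No intensities were analysed here, so signal over background is unknown.

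Before the data were examined, the tests, 22 gene lists, the alternatives and the rule for named genes were fixed. The text names 18 fixed genes of meiosis, DNA damage and reference use whatever their values, the 10 genes with the largest positive and the 10 with the largest negative slope among those past the threshold with a gene name, and in each list up to 2 members with the highest maximum and up to 2 with the lowest minimum of their values. Members of a list that passed the slope test were named in addition where they were few, and so were RPL43B and the genes with the highest and lowest value of all; these were chosen after their values were seen. HUG1 of the fixed genes has no row in the table. Results for some single genes are not reported here.

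Counts of genes at least 2-fold from 0 h (log2 of at least 1 or at most -1) and between neighbouring times are descriptions without a test, since each time has n = 1. List medians were set against 10000 random lists of the same size; these could not be matched on expression level. The trend over time was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as a line in hours with an intercept, with 5 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over 5585 genes. Scatter around the line is the only error estimate, so curved courses count as error, and arrays of one time course are not independent, so the p-values are a ranking with this limit. Lists were tested on the slope with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over 22 lists. Counts given as adjusted over the list alone use Benjamini-Hochberg on the limma p-values of that list's genes only. They correct neither over the 22 lists nor for members that move together, so they are descriptions. Descriptions used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots matplotlib 3.10.9.

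Both tests were tested on simulated data. For the time trend over 7 arrays, simulated for 5585 genes with the residual spread of the real ones, 20% of 50 genes with a slope of 0.25 log2 per hour were recovered, 74% at 0.5, 98% at 1 and 100% at 1.5, with 5 false calls among 151. The simulated errors were independent between genes and arrays, and the slopes were given to genes drawn at random. In the real data SPR28 and DIT1, with slopes of 1.23 and 1.09, did not pass (limma adjusted p = 0.0504 and 0.0520). The simulated recovery and false calls therefore do not carry over to steep genes with large scatter or to errors shared by genes. For lists of 25 among 1000 genes with no slope but a correlation of 0.5 between members, camera gave a p under 0.05 in 53.5% of 200 simulations at the preset correlation and in 4% with an estimated one. Uncorrelated lists with no slope gave 3% and 1.5%, and lists with a slope of 0.5 were found in 100% of simulations by both. Each simulated gene had the median residual standard deviation of 0.48, and genes outside the list had no slope. Rising genes of the real data scatter more around the line (SPS1 1.92, SSP2 1.84, GAS4 1.91). The 100% therefore does not carry over to lists of such genes, and a call lost with an estimated correlation is not evidence against a slope.

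Alternatives were columns centred on their median, quantile normalization between columns, every gene with a value at that time, genes with a value in at least 5 columns, the rank of the time in place of hours, robust eBayes, a quadratic in time, a filter on genes whose values span under 0.5, camera on ranks, and each array left out in turn. Peak times without the 6 h column and after centring, and list medians over genes listed at a time, were added after the data were seen. Centring moves all genes by the column median, at most 0.15 at 6 h.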

Results

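Transcript levels were followed through meiosis in budding yeast (Saccharomyces cerevisiae) carrying spo11-Y135F, an allele of the gene for Spo11, the protein that makes the DNA double-strand breaks of meiotic recombination; the exchanged tyrosine is the catalytic residue, so the protein is present without cleaving DNA. Samples were taken at 1, 2, 3, 4, 5, 6 and 8 h, and each time point has 1 array. On each array the Cy5 channel held mRNA of the time point and the Cy3 channel a mixture of mRNA from all time points, and the deposited value of a gene is the log2 of this ratio relative to the same ratio at 0 h. A value of 1 is therefore a transcript share 2-fold above that at 0 h. Of 6141 open reading frames in the table, 5585 had a value at all 7 times, and all counts refer to these unless stated otherwise. No wild-type strain was analysed here, so the comparisons are between times within the mutant. The values at one time have no replicate spread, so sizes at single times are descriptions of these arrays. If every column was divided by the same 0 h measurement, an error in it would shift all 7 values of a gene together. Whether the 6 h column, which has a different set of empty rows, shares that measurement is not given in the sources used here. The number of arrays limits the precision throughout.

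The first question the time course addresses is when the genes of entry into meiosis and of meiotic prophase are expressed in this strain. Genes of chromosome axis, meiotic cohesin and synapsis were the early group farthest above 0 h. Their median log2 ratio was 1.64 at 1 h, 3.80 at 3 h (13.9-fold above 0 h, quartiles 2.78 and 4.65 over 18 genes) and 1.52 at 8 h. All 18 were at least 2-fold above 0 h at 3 h. After quantile normalization the medians of the axis list at 3 h, the break formation list at 3 h and the histone list at 2 h were larger, with 4.75, 2.42 and 2.85 against 3.80, 1.70 and 1.93. REC8 (YPR007C), the meiotic cohesin subunit, was highest at 3 h with 5.99, and HOP1 (YIL072W), an axis protein, reached 5.21 at 3 h and 5.88 at 6 h. HOP1 was at 3.89 at 5 h and 2.8 at 8 h, so its highest value rests on the 6 h array alone. ZIP1 (YDR285W), the central element of the synaptonemal complex, was highest at 3 h with 4.70. The members with the lowest values, SPO16 and ECM11, lay near 0 at 1 h (-0.04 and 0.04) and at 2.66 and 2.69 at 3 h.

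Transcripts for double-strand break formation had a median of 1.70 at 3 h (11 genes, quartiles 0.57 and 2.43), with 7 of them at least 2-fold above 0 h. REC114 was at 4.10 and REC102 at 3.32 at 3 h, while RAD50 and NAM8, which also act outside meiosis, were lowest at 8 h with -0.86 and -1.15. The transcript of SPO11 itself (YHL022C) was highest at 4 h with 2.38 (5.20-fold above 0 h) and lay at -0.27 at 8 h. Between these times it was at 0.80 at 5 h and 2.12 at 6 h. The 6 h column departs more from its neighbours than those of 2 to 5 h, so a rise from 5 to 6 h rests on that array alone. Genes of strand exchange and repair had a median of 1.06 at 4 h over 11 genes, with wide quartiles of 0.49 and 3.94. DMC1 (YER179W), the meiotic recombinase, was highest at 3 h with 4.80, and MEI5, which assists it, at 6 h with 5.88. MEI5 was at 4.72 at 5 h and 2.11 at 8 h, so its highest value too rests on the 6 h array. SHU2 was lowest at 6 h with -1.31. Regulators of meiotic entry had a median of 1.18 at 3 h over 13 genes. IME1 (YJR094C), the master regulator of entry, was at 2.75 at 1 h and 3.50 at 3 h and was near 0 h again at 8 h with 0.23. IME2 (YJL106W), the kinase it activates, was highest at 4 h with 6.06, and SLZ1, a partner of the mRNA methyltransferase, at 4 h with 4.32. RIM11 at 1 h (-1.41) and RIM101 at 6 h (-1.10) had the lowest values of that list.

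Premeiotic replication genes were above 0 h early, with a median of 0.93 at 2 h over 27 genes and -0.07 at 8 h. POL30, the replication clamp, was at 2.84 and RFA3 at 2.58 at 2 h, and DPB2 and RFC2 had the lowest values with -1.49 at 8 h and -1.23 at 6 h. Histone transcripts moved within 1 hour from below to above 0 h: the median over 9 genes was -0.63 at 1 h and 1.93 at 2 h, when all 9 were at least 2-fold above 0 h. HHF2 was at 2.69 at 2 h. HTA2 and HHF1 were lowest at 1 h with -1.76 and -1.37. The linker histone gene HHO1 differed from the core histone genes, with its highest value, 3.06, at 5 h. Against 10000 random lists of the same size, the medians of the axis list exceeded the central 95% of random lists at all 7 times, those of the break formation list at 6 times and those of the histone list at 2 and 3 h. In the test of the slope over time, none of the genes of the axis, break formation, strand exchange and histone lists passed, over all genes or adjusted over the list alone; a straight line does not describe a rise followed by a fall. In the entry list 0 genes passed over all genes and 1 gene fell adjusted over the list alone. In the replication list 1 gene fell over all genes, MCM6 of the replicative helicase (slope -0.30 log2 per hour, limma adjusted p = 0.0496), and 7 fell adjusted over the list alone.

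**Figure D1:**
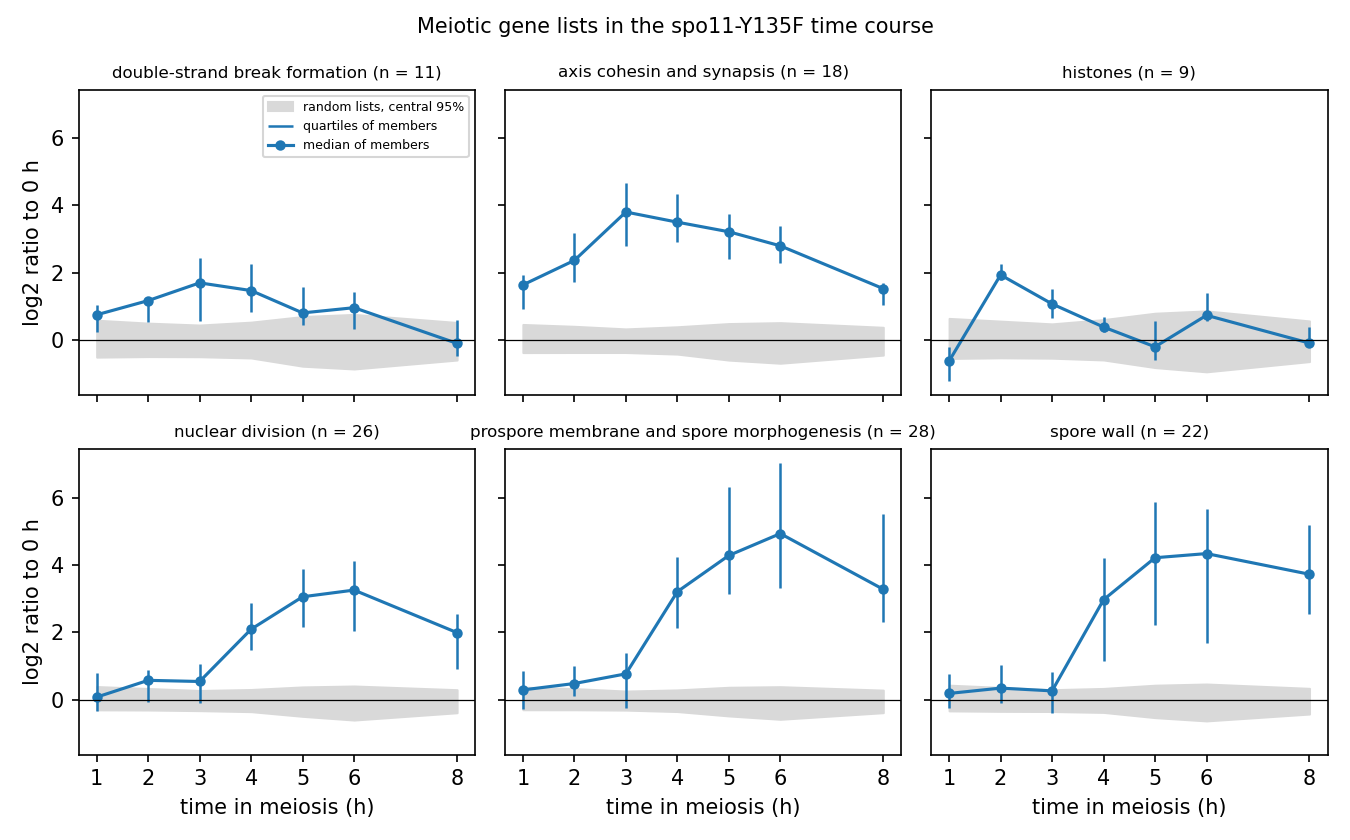
Median log2 ratio to 0 h (y axis) against hours in meiosis (x axis) for 6 gene lists; points are medians over the n genes of a list, vertical lines their quartiles, and the grey band the central 95% of medians of random lists of that size, with 1 array per time. The axis list is highest at 3 h (3.80), the histone list at 2 h (1.93), and the nuclear division (3.25), prospore membrane (4.93) and spore wall (4.34) lists at 6 h, values as deposited.

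A second question is whether and when the genes of the meiotic divisions and of spore formation follow. The step lay between 3 and 4 h. Over that hour the list median went from 0.54 to 2.09 for nuclear division (26 genes), from 0.77 to 3.21 for prospore membrane and spore morphogenesis (28 genes) and from 0.26 to 2.97 for the spore wall (22 genes). All 3 medians were highest at 6 h, with 3.25, 4.93 and 4.34, that is 9.54-fold, 30.5-fold and 20.2-fold above 0 h. After quantile normalization only the prospore membrane list was still highest at 6 h (3.38); nuclear division and spore wall were highest at 5 h, with 2.31 and 3.27 against 2.17 and 2.93 at 6 h. NDT80 (YHR124W), the transcription factor that starts the middle meiotic programme, was at 1.74 at 3 h, 5.17 at 4 h and 7.47 at 6 h. PES4 was highest at 6 h with 7.66. CLB1 (YGR108W), an M-phase cyclin, was below 0 h at 2 and 3 h with -2.57 and -2.46 and at 4.70 at 6 h. CDC5 (YMR001C), the polo kinase, was at -1.26 at 2 h, 0.07 at 3 h and 3.17 at 4 h. In the nuclear division list 1 gene rose over all genes tested, AMA1 (0.68 log2 per hour), a meiotic activator of the anaphase-promoting complex, and 12 rose adjusted over the list alone.

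The prospore membrane is the membrane that grows around each nucleus and closes into the spore. SPR28, a sporulation septin, and SPS2 were both highest at 6 h; SPR28 was at 9.11 then, and SPS2 was at 8.33 at 5 h already. SPO77 and SPO71 had the lowest early values, -1.51 and -1.10 at 1 h, and were at 3.17 and 1.86 at 4 h. SPS4 (YOR313C) differed from its list: its values stayed between 0.24 and 0.90. Signal over background is unknown, so a row that does not report its transcript cannot be told from a transcript that changed little. In this list 8 genes rose over all genes tested and 24 adjusted over the list alone, among them SPS1 (YDR523C), a sporulation kinase, with 0.23 at 3 h and 8.49 at 6 h. In the spore wall list 4 genes rose over all genes tested (SPS22, RRT12, GAS2 and GAS4) and 16 adjusted over the list alone. SPO19 was highest at 6 h with 8.30. The genes of the outermost, dityrosine layer came later: DIT1 (YDR403W) was at 0.55 at 5 h, 3.75 at 6 h and 8.52 at 8 h, and DIT2 (YDR402C) at 2.30 at 5 h and 5.72 at 8 h. SPS100 (YHR139C), a late spore wall gene, was at -1.29 at 6 h and 3.45 at 8 h. SWM1, a subunit of the anaphase-promoting complex, was lowest at 3 h with -1.24 and stayed below 0.14 throughout.

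Growth and metabolism were the next point of comparison. Ribosomal protein transcripts were far below 0 h from 1 to 5 h, with medians between -1.59 at 2 h and -2.31 at 5 h (4.97-fold below 0 h, quartiles -2.90 and -1.79 over 125 genes), and near it at 6 and 8 h with -0.34 and -0.59. At 5 h 113 of the 125 were at least 2-fold below 0 h, and at 8 h 20. RPL27A and RPS12 had the lowest values, -4.13 and -4.05 at 5 h. RPL19B was highest at 6 h with 1.70. RPL43B (YJR094W-A) stood apart with 3.65 at 3 h; its 7 values lay within 0.20 of those of IME1, the gene next to it. Ribosome biogenesis genes had a median of -0.81 at 5 h and 0.65 at 8 h (35 genes). DBP3, DRS1 and NOP58 rose over all genes tested, with DBP3, an RNA helicase, going from -1.18 at 1 h to 2.62 at 8 h (slope 0.60 ± 0.07 SE log2 per hour, limma adjusted p = 0.0265), and 12 rose adjusted over the list alone. RPA43 was highest at 6 h with 3.42, whereas RPA190, the largest subunit of the same RNA polymerase, was at -2.52 at 6 h; NOP15 was at -2.36 at 6 h.

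Glycolytic transcripts were below 0 h at every time, with a median of -0.78 at 1 h and -3.25 at 5 h (9.50-fold below 0 h, 18 of 19 genes at least 2-fold below). After quantile normalization the glycolytic median was lowest at 4 h (-2.90, against -2.71 at 5 h) and the ribosomal protein median at 3 h (-1.97, against -1.88 at 5 h). PGK1 was lowest at 6 h with -5.64 and ENO1 at 5 h with -5.22; PFK1 (0.18 at 6 h) and PDC5 (0.07 at 1 h) had the highest maxima. TPI1 fell over all genes tested, and 8 genes fell adjusted over the list alone. Genes of the glyoxylate cycle and gluconeogenesis had a median of 0.04 at 1 h and -1.74 at 8 h (17 genes), with opposite courses inside the list. FBP1, the gluconeogenic bisphosphatase, was below -3.83 at every time and lowest at 6 h with -5.96. PCK1 rose from -3.97 at 1 h to -0.46 at 8 h, while CIT3, YAT1 and YAT2 fell; ADY2, an acetate transporter, was highest at 4 h with 2.35. Adjusted over the list alone, 1 gene rose and 10 fell. The respiratory chain and ATP synthase list was lowest at 8 h with a median of -1.68 (28 genes), COX12 fell to -2.86 at 8 h, and 2 genes fell adjusted over the list alone; ATP2 was lowest at 5 h with -3.13, and COX7 (1.38 at 6 h) and ATP15 (0.90 at 2 h) had the highest maxima. The TCA cycle list stayed between -0.63 at 8 h and 0.16 at 4 h (15 genes), with 0 genes past the threshold over all genes and 3 falling adjusted over the list alone; FUM1 was at -2.27 at 8 h, SDH3 at 1.08 at 1 h and -1.81 at 8 h, and LSC2 at 1.55 at 6 h. Proteasome transcripts had a median of 0.67 at 3 h and -0.83 at 8 h (31 genes), with no gene past the threshold over all genes or adjusted over the list alone. PRE4 (1.46 at 1 h) and PUP1 (1.34 at 4 h) had the highest maxima, and PRE7 (-1.72 at 6 h) and PRE6 (-1.50 at 8 h) the lowest minima.

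**Figure D2:**
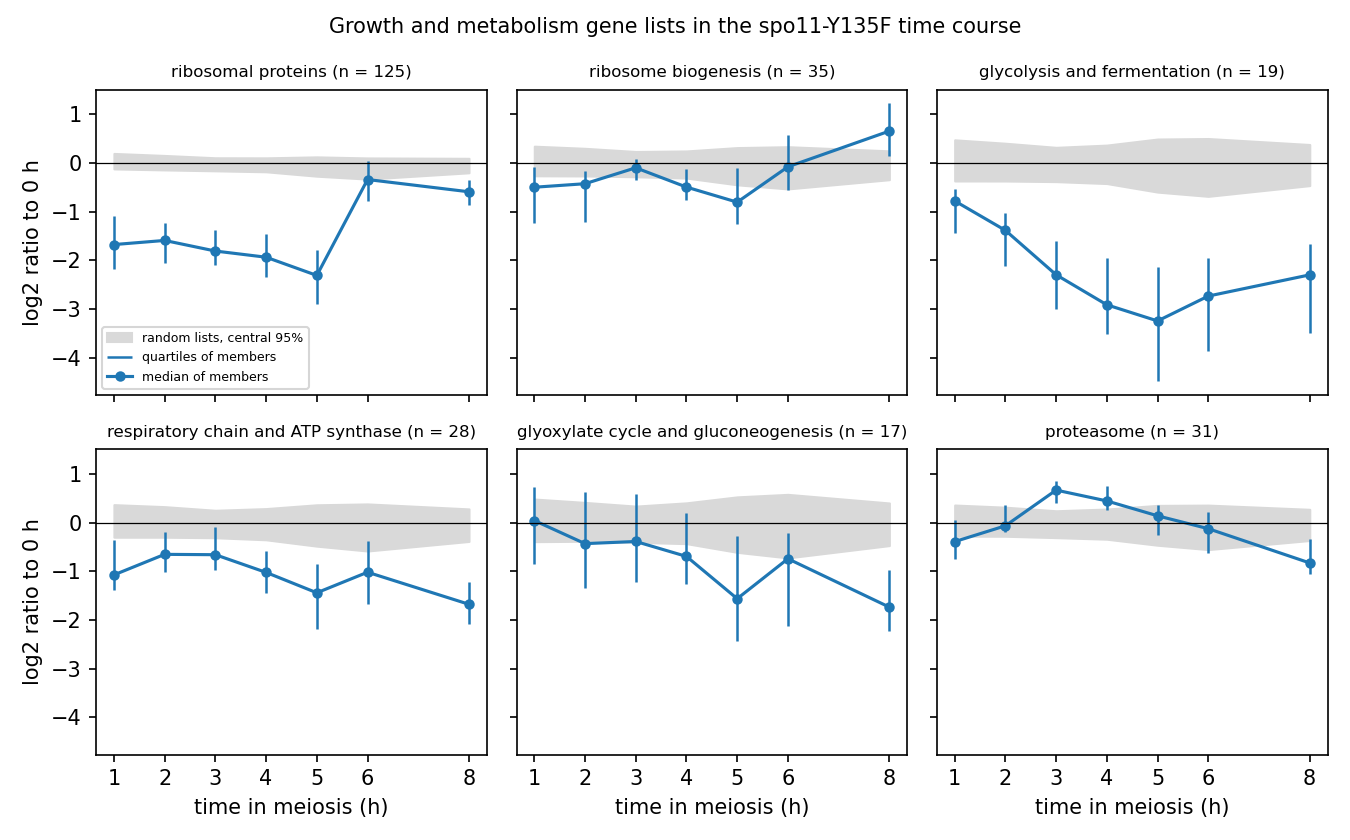
Median log2 ratio to 0 h (y axis) against hours in meiosis (x axis) for 6 lists of growth and metabolism; points, vertical lines and grey band stand for list medians, member quartiles and the central 95% of random lists, with 1 array per time. Ribosomal protein genes go from -2.31 at 5 h to -0.34 at 6 h, and glycolytic genes are lowest at 5 h (-3.25), values as deposited.

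The nutrient and stress lists held genes far above and genes far below 0 h. In the nitrogen starvation and autophagy list (31 genes, median 0.43 at 1 h and 0.06 at 8 h), DAL5, an allantoate permease, was at 4.65 and MEP2, an ammonium permease, at 3.15 at 1 h. At 5, 6 and 8 h MEP2 was at -1.14, -4.81 and 0.06, and GAP1, the general amino acid permease, at -2.62, -5.57 and -1.96. Their lowest values rest on the 6 h array, whose column departs more from its neighbours than those of 2 to 5 h. ATG8, needed for autophagosomes, rose from 0.30 at 1 h to 3.44 at 8 h, GLN1 rose too, and DAL2 and PUT1 fell; adjusted over the list alone 4 genes rose and 9 fell. Amino acid biosynthesis genes had a median of 0.31 at 1 h and -0.53 at 6 h (38 genes). LEU2 was at 2.74 at 1 h and ARG1 at -3.40 at 5 h, ARG8 at -2.25 at 6 h; LYS4 rose to 2.64 at 8 h and ARG3 fell from 2.02 at 1 h to -1.08 at 8 h, and adjusted over the list alone 1 gene rose and 2 fell. The stress and storage carbohydrate list was lowest at 6 h with a median of -1.01 (22 genes). After quantile normalization it was lowest at 1 h (-0.85, against -0.72 at 6 h). CTT1, the cytosolic catalase, rose from -1.32 at 3 h to 4.92 at 8 h, with 3 genes rising adjusted over the list alone, SSA3 was at 2.86 at 8 h, and GSY2 (-2.89 at 6 h) and TPS2 (-2.89 at 5 h) had the lowest minima. Among genes of G1 and budding the median was -0.79 at 3 h (18 genes); DSE1 and CTS1, which act in the separation of daughter cells, were at -4.32 and -3.67 at 6 h, AXL2 at 2.60 at 6 h and PCL1 at 1.68 at 1 h. In the list of haploid and mating-type specific genes (19 genes, median 0.60 at 5 h) STE3, the a-factor receptor, was at 4.60 at 6 h and AGA2, an agglutinin subunit, at 4.30 at 2 h; STE6 was at -1.61 at 5 h and MFA2 at -0.98 at 6 h. No gene of these last 2 lists passed over all genes, and 3 of the mating list rose adjusted over the list alone.

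The DNA damage response list was close to 0 h. Its median lay between -0.21 at 6 h and 0.34 at 2 h over 16 genes, within the central 95% of random lists at all 7 times, and none of its genes passed the slope test over all genes or adjusted over the list alone. RNR3 (YIL066C), a ribonucleotide reductase gene induced by DNA damage, stayed between -0.39 and 0.95. DDC1, a checkpoint clamp subunit, was at 2.69 at 3 h and DIN7, a mitochondrial nuclease, at 2.54 at 5 h. UBI4 was lowest at 1 h with -1.60 and RNR2 at 6 h with -1.60. HUG1, another damage-induced gene, was not measured. ACT1 (YFL039C), often used as a reference, was below 0 h at every time, between -0.79 at 3 h and -1.74 at 5 h.

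Over all genes, transcripts at least 2-fold from 0 h were most numerous at 5 and 6 h in the values as deposited, where the 6 h column also had the widest spread (standard deviation 1.49). Quantile normalization, by its construction, gave every time 719 genes above and 677 below, so it cannot test this ranking. How far the ranking rests on the spread of the columns was not separated. At 1, 2 and 3 h, 601, 485 and 429 genes were at least 2-fold above 0 h and 527, 522 and 471 at least 2-fold below. At 4, 5, 6 and 8 h the numbers above were 644, 909, 1056 and 685, and those below 599, 969, 1090 and 605. At some time 1948 genes were at least 2-fold above and 1965 at least 2-fold below 0 h, while 1918 stayed within 2-fold throughout. The highest value was that of PIR5, a sporulation cell wall gene, at 6 h (9.89), and the lowest that of FBP1 at 6 h. Of the 655 genes at least 4-fold above 0 h at some time, 312 peaked at 6 h, 128 at 5 h, 65 at 8 h, 55 at 3 h, 37 at 1 h, 33 at 2 h and 25 at 4 h. Of the 493 at least 4-fold below, 202 were lowest at 6 h and 158 at 5 h. With columns centred on their median this order turned, with 140 of 431 lowest at 6 h and 152 at 5 h.

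Differences between neighbouring times do not contain the 0 h measurement where both columns were divided by the same one. For the 6 h column, which has a different set of empty rows, this is not known. The counts from 5 to 6 h and from 6 to 8 h may therefore contain a difference at 0 h. From 1 to 2 h 321 genes differed at least 2-fold, from 2 to 3 h 639, from 3 to 4 h 407, from 4 to 5 h 662, from 5 to 6 h 1188 and from 6 to 8 h, over 2 hours, 1636. The interval from 3 to 4 h was the most one-sided, with 334 genes higher at 4 h and 73 lower; after quantile normalization between columns the numbers were 372 and 234. Quantile normalization, which gives each column the same spread, changed the counts of 5 of the 6 intervals by over 1.5 times, to 644 from 1 to 2 h, 1108 from 2 to 3 h, 343 from 4 to 5 h, 615 from 5 to 6 h and 1040 from 6 to 8 h.

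**Figure D3:**
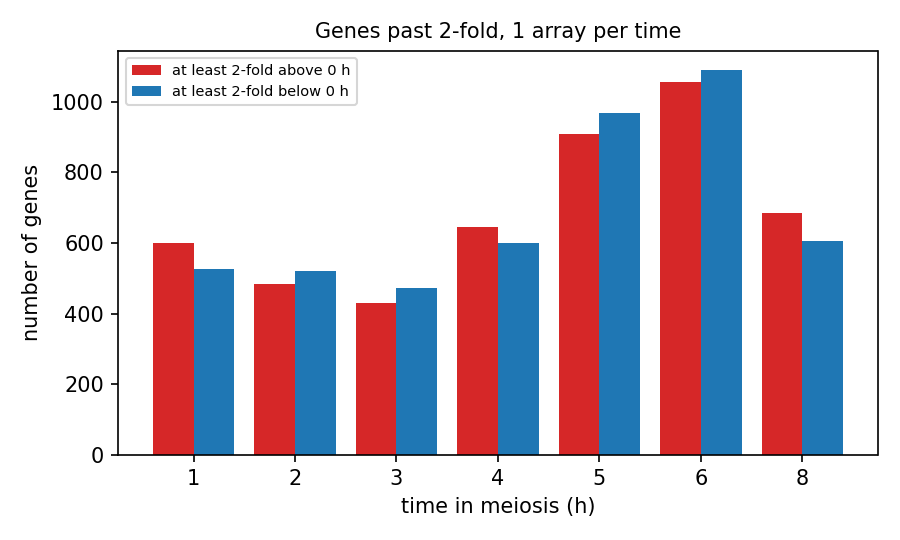
Number of genes (y axis) at least 2-fold above (red) and below (blue) 0 h at each time (x axis, hours in meiosis), of 5585 genes with a value at all times; each bar is 1 array and has no error. The bars are highest at 6 h, with 1056 genes above and 1090 below.

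A straight line over the 7 arrays asked which transcripts had a rising or falling slope over time, which a step can give as well as a steady course. With limma, 75 genes rose and 40 fell at a Benjamini-Hochberg adjusted p under 0.05. The 10 steepest rising genes with a gene name were PIR5, RRT5, SPS1, SPR2, SGA1, CTS2, SPR6, SPR1, SSP2 and GAS4. Among them are genes for cell wall and chitin turnover (PIR5, CTS2, GAS4), the sporulation glucoamylase SGA1 and the sporulation glucanase SPR1. PIR5 had a slope of 1.34 ± 0.28 SE log2 per hour (adjusted p = 0.0496) and SPR6 one of 1.16 ± 0.16 (adjusted p = 0.0420). The 10 slopes lay between 1.13 and 1.34, but the courses were not steady. PIR5 was at -0.27 at 3 h, 9.89 at 6 h and 7.45 at 8 h. Of the 10, only SPR6 was higher at 8 h than at 6 h. The 10 steepest falling genes were TPI1, PUT1, FIT2, CIT3, PST1, PDH1, DAL2, ARG3, LEE1 and PRY2, with slopes between -0.69 and -0.42. TPI1, triose phosphate isomerase of glycolysis, went from -0.62 at 1 h to -4.59 at 8 h (slope -0.69 ± 0.12 SE, adjusted p = 0.0477). PUT1, which degrades proline, went from 1.22 to -2.29, and FIT2, a cell wall mannoprotein for iron uptake, from -0.21 to -3.93. PDH1 and CIT3, both of the methylcitrate route, went from 0.65 to -2.31 and from 1.69 to -1.57.

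These calls stood near the threshold: the lowest adjusted p of all genes was 0.0240, and 1282 genes had an unadjusted p under 0.05. Without the 1, 2 or 6 h array 0 genes rose or fell, without the 3 h array 16 rose and 3 fell, without the 4 h array 4 rose and 0 fell, without the 5 h array 7 rose and 1 fell, and without the 8 h array 473 rose and 395 fell. All 115 slopes kept their sign in each of these fits, but the genes had been chosen for their slopes over these same arrays, so a change of sign was unlikely beforehand. With columns centred on their medians 55 rose and 16 fell, and after quantile normalization 229 rose and 201 fell.

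The slopes of the gene lists were compared with those of all other genes by camera. With its preset correlation, 6 of 22 lists shifted towards positive slopes and 5 towards negative slopes. The positive ones were prospore membrane (median slope 0.69 log2 per hour, adjusted p = 6.62e-16), ribosomal proteins (0.16, adjusted p = 9.22e-14), spore wall (0.69, adjusted p = 9.08e-12), nuclear division (0.43, adjusted p = 2.10e-10), ribosome biogenesis (0.13, adjusted p = 4.15e-06) and stress and storage carbohydrate (0.04, adjusted p = 0.0467). With an estimated correlation the adjusted p of these 6 was 0.437, 0.531, 0.349, 0.437, 0.437 and 0.531, in the same order, so that none passed. The stress list had a positive shift in slope although its median lay below 0 h from 1 to 6 h. The negative ones were premeiotic replication (median slope -0.13, adjusted p = 1.66e-05), glyoxylate cycle and gluconeogenesis (-0.23, adjusted p = 3.21e-05), respiratory chain (-0.13, adjusted p = 0.000532), glycolysis (-0.20, adjusted p = 0.000601) and proteasome (-0.09, adjusted p = 0.0349). With an estimated correlation their adjusted p was 0.437, 0.219, 0.531, 0.531 and 0.693, so that no list of the 22 held its call. Of the other 11 lists, the nearest to the threshold were amino acid biosynthesis and nitrogen starvation, both with an adjusted p of 0.0634. Single arrays decided some of these calls: without the 8 h array the shifts of the replication (adjusted p = 0.112), ribosome biogenesis (0.124) and respiratory (0.124) lists no longer passed and those of the proteasome (0.532) and stress (0.813) lists changed direction and did not pass, without the 1 h array that of glycolysis (0.0637), without the 3 h array that of the proteasome (0.107) and without the 5 h array that of the stress list (0.0558) did not pass. In the other direction, further lists passed without single arrays: without the 1 h array break formation (adjusted p = 0.000731), strand exchange (0.00137), axis (0.000172) and histones (0.00227), without the 2 h array amino acid biosynthesis (0.0369) and nitrogen starvation (0.0443), and without the 3 h array G1 and budding (0.0417), all towards negative slopes. Without the 8 h array amino acid biosynthesis (0.00131) and nitrogen starvation (0.0250) passed too, and the axis list passed towards positive slopes (0.00281).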

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

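The comparison of the 6 h column with lines between times 3 hours apart, and the test of whether the ribosomal protein values at 6 h rest on that array, were chosen after the values were seen. The bootstrap interval of the matched-gene share was also added after that share was seen, and it changed the reading of the test from against the explanation to open. Groups of 1 array per time could not be searched for samples far from the others, and no contrast was repeated in a second group.

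An excess of rows above 0 h appeared in data that the comparisons do not use. Of the 321 open reading frames with a value at 6 h only, 84 (26.2%) were at least 2-fold above 0 h and 45 (14.0%) at least 2-fold below, against 18.9% and 19.5% of the genes with a value at all times. These rows were selected by having a value at 6 h alone, and how rows were kept or processed at 6 h is unknown. The shares therefore cannot separate transcript changes from that selection. Of the 321, 290 have a match in the reference table. The highest were PFS1 (YHR185C), a gene of prospore formation, with 6.32, HAB1 (YBR285W) with 5.82 and YOR365C with 4.95; the lowest were CTF19 (YPL018W), a kinetochore gene, with -3.32 and SOG2 (YOR353C) with -2.72. These genes were named after their values were seen, and each rests on 1 value.

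The 6 h column departs from its neighbours. Among genes outside the lists whose values at the times before and after lie within 0.5 of each other, the robust standard deviation of the departure from the line between these times was 0.74 at 6 h, against 0.37, 0.38, 0.27 and 0.50 at 2, 3, 4 and 5 h, a ratio of 1.951 to their median; over equally long intervals of 3 hours it was 0.37 at 2 h and 0.54 at 3 h. This is what a noisier array, or one processed apart from the others, would give, and the different set of empty rows at 6 h is consistent with such a difference. Departures shared by the genes of a list also occurred: 7 of the 22 lists had a median departure at 6 h outside the central 95% of random lists, with ribosomal proteins at 1.27, prospore membrane at 0.67 and stress genes at -0.81. The random lists were drawn gene by gene and not matched on expression level. This count therefore cannot separate transcript changes from an array processed apart. Both may contribute, and with 1 array at 6 h their shares stay open.

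Ribosomal protein transcripts were nearer to 0 h at 6 and 8 h than at 5 h. The list median at 8 h lay 1.7186 above that at 5 h, which restates the pattern and so is no separate test of the 6 h array. Signal shared between duplicated genes is argued against: the 16 genes without a duplicate differed between 5 and 8 h by 1.149 times as much as the 109 with one (medians 1.99 and 1.73). A general return of transcripts low at 5 h stays open. For 125 other genes matched on their 5 h value the median difference was 0.84, against 1.75 for the ribosomal protein genes. That is a share of 0.48 (95% bootstrap interval 0.38 to 0.69). The bootstrap resampled matched pairs of genes measured on the same 5 h and 8 h arrays, so the interval leaves out the error of these arrays. The 5 h value is also both the matching value and part of the difference. The share therefore decides for neither a full nor a partial account. A change in the expression of ribosomal protein genes late in the course is a hypothesis that needs more arrays.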

How the results depend on the processing

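Peak times without the 6 h column and after centring, and list medians over the genes listed at a time, were chosen after the data were seen. The spread among replicates being unknown, an untested value counts as moved here when it shifts by the median residual standard deviation of the trend fit, 0.48, or more. All 7 counts of genes above and all 7 of genes below 0 h stayed within 1.5 times with centred columns and with every gene that has a value at that time. Quantile normalization, by its construction, gives 719 genes above and 677 below at every time, which moved the counts at 3 h (above) and 6 h (below) by over 1.5 times; it also gave 644, 1108, 343, 615 and 1040 genes differing between 1 and 2 h, 2 and 3 h, 4 and 5 h, 5 and 6 h, and 6 and 8 h. It moved 7 of 22 list medians at their most extreme time without changing a sign, to 4.75 for axis, 2.42 for break formation, 2.85 for histones, 2.17 for nuclear division, 3.38 for prospore membrane, 2.93 for spore wall and -2.71 for glycolysis; centring and the genes listed at that time moved none. Without the 6 h column 281 genes peaked at 5 h, because genes with their maximum at 6 h take their next highest time; the other peak and lowest-time counts stayed within 1.5 times.

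Genes rising over time numbered 229 after quantile normalization and 226 on the rank of the time. Genes falling numbered 201 and 141 in those settings and 16 with centred columns. The cause was not tested. With a quadratic the numbers were 176 and 141. That setting tested line and curve together and took the direction from the fitted value at 8 h minus that at 1 h. Its counts can therefore hold curved courses and are not counts of slopes. The 3 other settings gave 70 to 94 rising and 38 to 47 falling. Leaving out 1 array in turn gave 0 to 473 rising and 0 to 395 falling genes. The 6 fits without 1 of the arrays up to 6 h gave fewer than the full fit, and the one without 8 h gave more. All 115 called genes kept their sign throughout, which is little support, since they were chosen for their slopes over these arrays. Of the 20 genes named for their slope, 14 passed with centred columns, 19 without the 8 h array, 6 without the 3 h array, 2 without the 5 h array and 0 without each of the others. Of 100 orders of the 7 arrays, the real one included, 3 gave at least 115 genes; the share of 2 in the 99 other orders has an exact 95% interval of 0.246% to 7.11%, added after the count was seen, so these draws leave open whether chance is excluded at 0.05. The highest other number was 453, several times the real one, and 95 of the other orders gave 0. The order with 453 gave the arrays of 1 to 4 h later times than those of 5 to 8 h. It thus still kept early and late arrays apart.

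Lists with positive slopes numbered 0 with an estimated correlation, and those with negative slopes 0. That setting changes the correlation, estimated at 0.0243 to 0.831 over the lists, and also lowers the degrees of freedom, and the parts of the 2 were not separated; in simulated lists with a correlation of 0.5 and no slope the preset called 53.5% and the estimate 4%. Quantile normalization gave 6 positive and 9 negative, centred columns 6 and 6, the rank of the time 5 and 6 and camera on ranks 5 and 5. On the rank of the time the proteasome and stress lists no longer passed (adjusted p = 0.105 for both) while amino acid biosynthesis (0.0318) and nitrogen starvation (0.0428) did, and with camera on ranks stress did not pass (0.0515). Leaving out 1 array gave 5 to 6 positive and 4 to 8 negative. Among lists that passed with all arrays or without the 8 h array, leaving out 8 h reversed the direction of 3: axis to positive slopes (adjusted p = 0.00281), proteasome to positive (0.532) and stress to negative (0.813). With each array left out in turn the adjusted p ran from 0.000172 (without 1 h) to 0.873 (without 3 h) for axis, from 1.28e-06 (without 1 h) to 0.532 for proteasome and from 0.000813 (without 6 h) to 0.813 for stress. Of the 100 orders, 49 gave at least the 11 lists of the real order and the highest other gave 17, so chance is not excluded for the number of lists. No paired analysis was possible because each time has 1 array and the columns carry no culture number. Counting each probe on its own was not run, because the table has 1 row per gene. Signal over background, which limits an array's low values, is unknown here.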

Other observations

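The families below were formed from gene names, and the test of unmatched reading frames was chosen, after the data were seen; medians are over the members with a value at all times, and signs of these medians hold with centred columns and after quantile normalization. Of 7 septin genes, 4 were at least 2-fold above 0 h at 5 h: SPR28, SPR3, CDC3 and CDC10 were at 7.72, 6.43, 3.90 and 2.80 at 5 h, while CDC11, CDC12 and SHS1 were at 0.21, -0.13 and 0.07. Genes of iron uptake had a median of -2.49 at 6 h over 9 genes; FET3 was at -3.98, FTR1 at -2.49 and ARN2 at -2.53, but FET5, a vacuolar relative of FET3, was at 1.84. Hexose transporters, 15 genes with a median of 1.03 at 5 h, included HXT14 with 9.05 at 6 h and HXT10 with 5.03 at 8 h, while HXT2 was at -3.92 at 6 h.

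Seripauperins, a family of near-identical genes for which signal shared between probes was not tested, had 14 of 16 genes at least 2-fold above 0 h at 8 h, with a median of 1.69. Purine synthesis genes had a median of -1.59 at 5 h over 11 genes and ergosterol genes one of -1.19 at 6 h over 19 genes. Mitochondrial ribosomal protein genes, 59 in number, had medians of -0.36, -0.47, -0.54 and -0.56 at 1, 2, 3 and 4 h, -0.26 at 5 h, 0.18 at 6 h and -0.48 at 8 h; like those of the cytosolic list, these were highest at 6 h. Translation factors, 16 genes, had a median of -1.45 at 1 h and -0.09 at 8 h.

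Some rows may report the transcript of the gene next to them. Reading frames without a match in the reference table had a correlation above 0.9 over the 7 times with a reading frame next in name in 31 of 374 cases (8.29%) and with one 10 places away in 12 of 383 (3.13%), a ratio of 2.645. YPR077C with YPR078C, YGL102C with RPL28 and YLR076C with RPL10 are such pairs. Among genes of the reference table a correlation above 0.9 occurred in 2.63% of 5134 adjacent pairs and 1.64% of 4990 pairs 10 places apart. These shares are of single pairs, whereas an unmatched reading frame took the higher of its correlations to either side. The median correlation was 0.135 for adjacent pairs and 0.063 for those 10 places apart, a difference of 0.0721. This lay between the bounds set for and against it, so an effect of neighbours stays open. By orientation the difference was 0.120 for divergent, 0.102 for convergent and 0.0376 for tandem pairs; bounds had been set only for all pairs together. RPL43B, whose values lay within 0.20 of those of IME1 next to it, is a candidate case that was picked after its values were seen.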
